A study of Mus musculus with 6 samples.

How the data were processed

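RNA sequencing had been done on 6 libraries of RAW264.7 cells, 3 labelled as HFCS-treated and 3 as control. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with standard Illumina methods. The growth protocol, which names the HFCS treatment, is the same text for every sample, so the groups were taken from the sample titles, as also given by the treatment labels. The deposited values are raw read counts per gene, whole numbers that are not normalised. Per the submitters' processing notes, the tools were CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3 on genome build mm10, with no order or settings given. The annotation release, the strand setting and any filter are not given in the sources used here. Where genes overlap, their reads therefore cannot be told apart, and 53 of the 172 named genes overlap another listed gene. The table holds 24379 genes with Ensembl identifiers and coordinates. GENCODE M21 held 24369 of them, 23705 (97.3%) with the same chromosome, start, end and strand. Symbols were matched for 24344 identifiers and not for 35, and 3 symbols of the gene lists were found under an older name. No column of other samples and no total or unassigned entry was in the table.

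Total counts per library were 13108485 to 15340255, and 3 counts, used as the floor for a gene not counted, correspond to 0.196 to 0.229 CPM per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Shares of counts were given exact Clopper-Pearson 95% intervals, and ratios with 1 to 3 counts in a group an exact binomial interval.

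Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 14360 genes and removed 10019. Library sizes were scaled by TMM, and CPM values, a gene's counts relative to its library's size, were computed with those sizes. The groups were compared with edgeR 4.0.16 (R 4.3.3), using glmQLFit and glmQLFTest with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes. Each SE was derived from the log2 fold change and its F statistic. The common biological coefficient of variation was 0.0984. An adjusted p under 0.05 counted as a change, with 2-fold as a further limit where stated. Fixed before the data were examined, 41 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry, where at least 5 members were tested. For each list the counts of genes past the threshold were also computed with the adjustment over the list alone. Adjusted p-values given with single genes are from edgeR's quasi-likelihood test, and those given with lists are from camera.

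The rule for named genes was fixed before the data were examined as well. It took the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM, groups that did not overlap and a proper gene name, then 16 genes chosen for the question, such as Tnf, Nos2, Khk and Akr1b3, and up to 4 genes with the smallest adjusted p from each list. This gave 172 tested genes, and other genes that are named are said to be so. Some genes are not reported here.

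The fit was tested on simulated data. Counts for 14360 genes were drawn from the means of the control-labelled libraries and from the library sizes and spreads of this comparison, with 200 genes changed. Of those that passed the filter among 13962 tested genes, the test recovered 55.1% at 1.5-fold, 79.2% at 2-fold, 93.8% at 3-fold and 100% at 4-fold, and 16 of 174 calls (9.20%) were false. Alternatives fixed beforehand were median-of-ratios, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 10 counts in each library of a group, the replicate number as a block, other fold limits and each library left out in turn. Removal of each library's trend on GC content and length, and library sizes without the 10 most abundant genes, were chosen after seeing the data, as was camera with median-of-ratios scaling and with the filter of 10 counts. Camera was not run with DESeq2 or limma-voom. Values of GC content and length were found for 99.9% of tested genes.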

Results

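Gene expression was measured by RNA sequencing in RAW264.7 cells, a macrophage-like line that grew from a mouse tumour induced by Abelson leukaemia virus. The labels put 3 libraries in a group treated with high-fructose corn syrup (HFCS), a sweetener of free fructose and glucose, and 3 in a group that they call WT, here the control. What the control cells received, and any osmotic control among it, is not given in the sources used here. Every sample carries a time of 18 h. The dose is given as 140 mM in the sample titles and treatment labels and as 170 mM in the source names, so it is uncertain which was used. Total counts were 13108485, 14948794 and 15340255 in HFCS replicates 1 to 3 and 14840315, 14101303 and 14530130 in control replicates 1 to 3, and the totals of the groups overlapped (two-sided exact permutation p = 1, n = 3 each). With 3 libraries against 3, such a test cannot give a p below 0.1. Other measures did part the groups, each at a permutation p of 0.1. The 10 most abundant genes held 6.16 ± 0.158% of counts in HFCS and 8.39 ± 0.230% in control libraries (mean ± SD). The TMM factor was 1.03 against 0.973 and the protein-coding share 96.3 ± 0.197% against 95.8 ± 0.268%. The number of genes with a count did not part them (permutation p = 0.2). Nothing in the labels says whether the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

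The comparison asked which genes differ between HFCS-treated and control macrophages, with inflammatory, NF-kB and oxidant genes named as the interest by the title of the series. Genes of inflammation, NF-kB subunits and targets, and genes of the early response to stimuli were higher in the HFCS-labelled libraries. Genes of mitosis, cholesterol synthesis, the tricarboxylic acid cycle and the antioxidant response were lower there. Camera made these 7 list calls with a preset correlation, and 0 of them held with an estimated correlation, where their adjusted p was 0.116 to 0.183. Lcn2, which codes for the iron-sequestering protein lipocalin 2, was 41.9-fold higher in the HFCS-labelled libraries, and Akr1b3, the aldose reductase that makes sorbitol, was 35.7-fold higher in the control-labelled libraries. The libraries are named by their labels throughout, because Akr1b3 and other genes that cells are known to raise in hypertonic medium lay at the lower level in the HFCS-labelled libraries. Every direction given here rests on those labels. The osmolarity of the media is not given in the sources used here.

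Of 14360 genes tested, 6447 (44.9%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 3223 were higher and 3224 lower in the HFCS-labelled libraries. At least 2-fold changes were found for 1528 genes, 609 higher and 919 lower. At least 4-fold changes were found for 111 higher and 237 lower genes. The median size of the change among genes that passed was 0.58 on the log2 scale. The groups' libraries did not overlap for 7833 genes (54.5%), where chance gives 10%. Scaling by library size alone, without correction for composition, gave 3975 higher and 2624 lower genes, so that 60.2% of the calls were higher in place of 50.0%, and it moved the median log2 fold change of all tested genes to 0.08. The first principal component held 70.0% of the variance and parted the groups. On the second, with 11.8%, control replicate 1 lay at 29.3 while control replicates 2 and 3 lay at -14.2 and -13.4; without control replicate 1 the test called 7550 genes. Pearson's r across genes was 0.985 to 0.991 within groups and 0.953 to 0.962 between them, and genes are not independent replicates. No libraries agreed within sampling noise, with a chi-square per degree of freedom of 2.60 to 16.7 within groups. All 162 named genes that passed the test were higher in every library of 1 group than in any of the other. The naming rule required this of the 8 highest and 8 lowest genes and favoured it in genes taken for a small adjusted p.

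The highest fold changes by the fixed rule belonged to Lcn2, Sh2d6, Ccl2, Fos, Ccl7, Cxcl2, Abca1 and C3ar1. Lcn2 (ENSMUSG00000026822, mm10 chromosome 2, 32384633 to 32388252, minus strand) had 208 ± 9.15 CPM (counts relative to the scaled library size) in HFCS-labelled and 4.96 ± 1.54 CPM in control-labelled libraries (mean ± SD, n = 3 each), a log2 fold change of 5.39 ± 0.15 (SE) with an edgeR adjusted p of 5.4e-09. The adaptor gene Sh2d6 rose by 3.92 and the complement receptor gene C3ar1 by 2.88 on that scale. The lowest belonged to Scel (-5.64), Gucy2g (-5.25), Akr1b3 (-5.16), Thsd4 (-5.01), Accsl (-4.97), Klhl30 (-4.20), Fam213a (-4.10) and Paqr5 (-4.06). Akr1b3 was among the most abundant messages of the control-labelled libraries, taking 0.693 to 0.760% of their counts against 0.0200 to 0.0223% in the HFCS-labelled ones. The exact 95% binomial limits were 0.689 to 0.697% for control replicate 1 and 0.0215 to 0.0231% for HFCS replicate 1, and such limits cover counting error only. Scel, which codes for the keratinocyte protein sciellin, was counted 9 times over the 3 HFCS-labelled libraries and 442 times over the control-labelled ones.

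**Figure D1:**
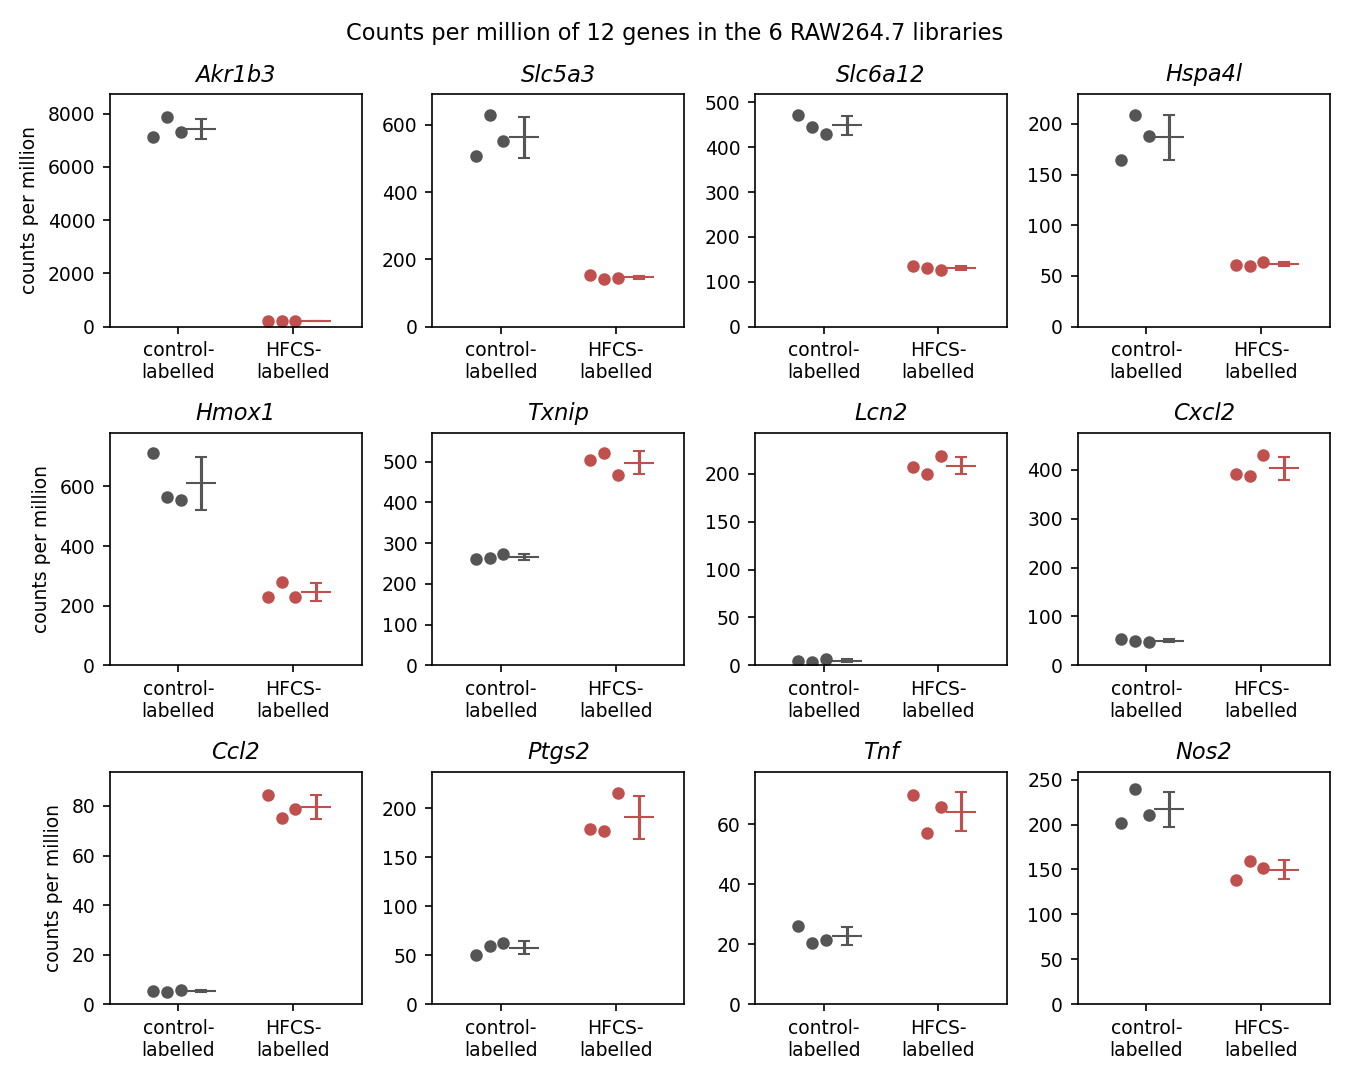
CPM (vertical axes, from 0, each gene on its own scale) of 12 named genes in the 3 control-labelled (grey) and 3 HFCS-labelled (red) libraries. Points are libraries, and the bar beside them is the mean with 1 SD to each side. No gene's groups overlap, and Akr1b3, Slc5a3, Slc6a12, Hspa4l, Hmox1 and Nos2 are lower in the HFCS-labelled libraries while the other 6 genes are higher.

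Inflammatory genes were higher in the HFCS-labelled libraries as a group, while the nitric oxide synthase gene Nos2 was lower. Of 24 tested genes for pro-inflammatory cytokines and effectors, 16 rose, 2 fell and 6 did not pass the test (17 and 2 adjusted over the list alone), with a median log2 fold change of 1.05. Camera called the list (adjusted p = 2.8e-05), but not with its correlation estimated (adjusted p = 0.116 with an estimated correlation). The cytokine gene Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007, minus strand) had 64.3 ± 6.44 against 22.6 ± 2.97 CPM, a log2 fold change of 1.5 ± 0.11 with an edgeR adjusted p of 4.6e-06. Ptgs2, which codes for the inducible cyclooxygenase of prostaglandin synthesis, had 190 ± 21.7 against 57.3 ± 6.63 CPM and Acod1, the enzyme that makes itaconate, 120 ± 20.9 against 22.4 ± 1.61 CPM. Il1b (chromosome 2, 129364570 to 129371139, minus strand) rose by 4.18 on the log2 scale but stayed low at 6.58 ± 1.25 against 0.354 ± 0.307 CPM, and its antisense gene Il1bos shares its position. Il6 (chromosome 5, 30013114 to 30019981, plus strand) was counted 74 times over the HFCS-labelled and 2 times over the control-labelled libraries, a ratio of 35.1 with a 95% counting interval of 9.37 to 295 and an edgeR adjusted p of 4.5e-04. Nos2 (chromosome 11, 78920787 to 78960254, plus strand) fell from 217 ± 19.5 to 150 ± 11 CPM, a log2 fold change of -0.53 ± 0.08 with an edgeR adjusted p of 4.5e-04. Here and below, some further members of the lists are named, chosen after their values were seen unless the fixed rule had picked them.

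Chemokine genes moved both ways. Ccl2 (chromosome 11, 82035571 to 82037453, plus strand), the monocyte attractant, rose from 5.28 ± 0.548 to 79.6 ± 4.66 CPM, and Cxcl2 (chromosome 5, 90903871 to 90905938, plus strand), a neutrophil attractant, from 50.5 ± 3.66 to 402 ± 23.4 CPM, each with an edgeR adjusted p of 5.4e-09. Ccl7, Ccl4 (0.53) and Cxcl14 (0.66) rose as well, while Ccl5 (-1.86) and Ccl9 (-0.63) fell and 6 of the 13 tested genes did not pass (the counts adjusted over the list alone were the same). The list's median log2 fold change was -0.02 (-0.051 to 0.171 over the settings tried) and its mean 0.63, with camera's direction upward and an adjusted p of 0.289 (0.595 with an estimated correlation).

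Genes of the NF-kB pathway, the transcription factor family that drives many inflammatory genes, were higher in the HFCS-labelled libraries. Of 36 subunits, feedback genes and targets, 18 rose and 3 fell (20 and 3 adjusted over the list alone), with a median of 0.58 and a camera adjusted p of 3.9e-04 (adjusted p = 0.116 with an estimated correlation). The subunit gene Nfkb1 (chromosome 3, 135584655 to 135691547, minus strand) had 225 ± 3.24 against 106 ± 3.62 CPM, and log2 fold changes were 1.09 for Nfkb1, 1.35 for Nfkb2, 0.90 for Rela and 1.03 for the inhibitor gene Nfkbia. The 3 that fell were Gadd45b (-1.87), Malt1 (-0.54) and Tnip1 (-0.30). Of 29 Toll-like receptor and NF-kB signalling genes, 15 rose and Ikbkg (-0.30) fell (15 and 2 adjusted over the list alone), with a camera adjusted p of 0.00147 (adjusted p = 0.335 with an estimated correlation). The lipopolysaccharide co-receptor gene Cd14 reached 409 ± 38.4 against 110 ± 2.64 CPM, and Tlr2 and Irak3 rose by 0.87 and 1.26 on the log2 scale.

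Lists next to these were not called by camera. Of 17 inflammasome and pyroptosis genes, 9 rose, among them Nlrp3 (1.60) and Casp4 (0.97), and 4 fell, Ninj1 (-1.18), Aim2 (-0.67), Gsdme (-0.54) and Nek7 (-0.29), with a camera adjusted p of 0.185. Of 27 interferon-stimulated genes, 7 rose, including Parp14 (1.77) and Irgm1 (0.93), and 5 fell, among them Usp18 (-0.91), Dhx58 (-0.72), Oas3 (-0.42) and Stat2 (-0.34), with a camera adjusted p of 0.229. Of 8 tested markers of alternative macrophage activation, Vegfa (1.45), Klf4 (1.53), Il4ra (0.98) and Stab1 (0.43) rose and Clec10a (-0.48) fell, with a camera adjusted p of 0.0636. Counts adjusted over the list alone were the same for these 3 lists.

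Genes of the antioxidant response controlled by the transcription factor NRF2 were lower in the HFCS-labelled libraries. Of 40 tested, 24 fell, 3 rose and 13 did not pass (the counts adjusted over the list alone were the same), with a median log2 fold change of -0.42 and a camera adjusted p of 2.5e-04 (adjusted p = 0.116 with an estimated correlation). The haem oxygenase gene Hmox1 had 246 ± 28.7 against 610 ± 87.6 CPM, and Nqo1, a quinone reductase, 0.438 ± 0.366 against 7.80 ± 0.466 CPM. Me1 (-1.91), the catalase gene Cat (-1.02) and the glutathione peroxidase gene Gpx1 (-0.99) fell as well. Sqstm1 (1.13), Srxn1 (0.63) and Fth1 (0.19) rose. Of 13 tested genes for NADPH oxidase and other sources of reactive oxygen, 6 rose and 2 fell (6 and 4 adjusted over the list alone), with a camera adjusted p of 0.435. Cybb, the catalytic subunit of the phagocyte oxidase, had 63.0 ± 3.98 against 19.3 ± 2.62 CPM, Ncf4 (0.48) and Cybc1 (0.61) rose, and Ncf1 (-0.45) and Maoa (-0.62) fell.

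Genes of the osmotic stress response moved apart, with Akr1b3, Slc5a3, Slc6a12 and Hspa4l lower and Aqp9 and Sgk1 higher in the HFCS-labelled libraries. Akr1b3 (ENSMUSG00000001642, chromosome 6, 34302434 to 34317478, minus strand) had 208 ± 12 against 7435 ± 381 CPM, a log2 fold change of -5.16 ± 0.08 with an edgeR adjusted p of 5.2e-11. The myo-inositol transporter gene Slc5a3 had 146 ± 5.42 against 562 ± 60.9 CPM, the betaine transporter gene Slc6a12 131 ± 4.21 against 450 ± 21.2 CPM and the chaperone gene Hspa4l 61.6 ± 1.97 against 187 ± 22.1 CPM. Of the list's 23 tested genes, 11 fell, 8 did not pass and 4 rose (12 fell and 5 rose adjusted over the list alone), and the 4 were Aqp9 (1.19), Sgk1 (1.63), Slc38a2 (0.42) and Map3k3 (0.33). The median was -0.18 and the mean -0.79, and camera did not call the list (adjusted p = 0.0636, and 0.384 with an estimated correlation), though it did without HFCS replicate 1 (0.0495), without a filter on low counts (0.0351) and with the trend on GC content and length removed (0.0460), the range over the 14 other settings in which camera was run with the preset correlation being 0.0351 to 0.128.

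Genes known to respond to glucose through the transcription factors MondoA and ChREBP did not move together. Txnip, the best-known target, rose from 266 ± 7.29 to 497 ± 28.2 CPM, a log2 fold change of 0.90 ± 0.07 with an edgeR adjusted p of 3.7e-06, and its relative Arrdc4 rose by 1.55. Tkfc (-0.85), Bhlhe40 (-0.47) and Klf10 (-0.25) fell, and 5 of the 10 tested genes did not pass (the counts adjusted over the list alone were the same). The median was -0.23 (-0.264 to -0.041 over the settings tried), the mean 0.00 and the camera adjusted p 0.542, downward. Of 14 tested genes for hexose transport and fructose metabolism, Slc2a3 (0.53) rose and Aldoc (-1.51), Tkfc, Ldha (-0.28), Slc2a1 (-0.28) and Slc2a9 (-0.26) fell, with a camera adjusted p of 0.497 and the same counts adjusted over the list alone. Slc2a1 did not pass without HFCS replicate 1 (edgeR adjusted p = 0.0845). Khk, which codes for the enzyme that phosphorylates fructose, had 24.3 ± 3.46 against 20.9 ± 4.73 CPM (edgeR adjusted p = 0.323), though without control replicate 1 its log2 fold change of 0.41 passed (edgeR adjusted p = 0.0207). The fructose transporter gene Slc2a5 was too low to test, with 9 counts over the HFCS-labelled and 16 over the control-labelled libraries.

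Among genes of the tricarboxylic acid cycle and of glycolysis that passed the test, more were lower than higher in the HFCS-labelled libraries. Of 24 genes of the tricarboxylic acid cycle, 15 fell, Dlst (0.22) rose and 8 did not pass, with the same counts adjusted over the list alone, with a median of -0.33 and a camera adjusted p of 2.3e-04 (adjusted p = 0.116 with an estimated correlation). The pyruvate carboxylase gene Pcx had 47.2 ± 3.16 against 172 ± 20.5 CPM, and Idh1 (-0.87) and Suclg2 (-0.95) fell. Of 28 glycolysis gene identifiers, 12 fell, 2 rose and 14 did not pass (13 and 2 adjusted over the list alone), with a camera adjusted p of 0.0144 (adjusted p = 0.528 with an estimated correlation). The pyruvate kinase gene Pkm had 3671 ± 206 against 6801 ± 458 CPM, and Pfkm fell by 1.28 on the log2 scale. The lactate exporter gene Slc16a3 (0.61) rose. Aldoa is listed under 2 identifiers, of which one fell (-0.60) and the other rose (0.56), so its change is uncertain. Of 26 hypoxia-response genes, 6 rose and 7 fell, with the same counts adjusted over the list alone, and Hif1a was at -1.02. Their median was -0.04 (-0.177 to 0.042 over the settings tried) but their mean 0.06, and the camera adjusted p was 0.649.

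Of 58 nuclear genes of oxidative phosphorylation, 17 fell, among them Ndufs8 (-0.78) and Uqcrh (-0.87), 6 rose and 35 did not pass, with a camera adjusted p of 0.145. Of 14 mitochondrially encoded genes, mt-Rnr1 (-1.30), mt-Co1 (-0.63) and mt-Nd3 (-1.01) fell and 11 did not pass, with a camera adjusted p of 0.0919. Without control replicate 1 camera called this list (adjusted p = 0.00620), while with all libraries the list had an adjusted p = 0.651 with an estimated correlation, and with the trend on GC content and length removed its adjusted p was 0.351. Without control replicate 2 mt-Nd3 did not pass (edgeR adjusted p = 0.0594), nor with that trend removed (0.0521), and mt-Nd2 (-0.46, edgeR adjusted p = 0.0874) passed without HFCS replicate 3 (0.0190) or without control replicate 1 (5.8e-04), without a filter on low counts (0.0280) and with the replicate number as a block (0.00114). The mitochondrial share of counts was 1.89 ± 0.194% in the HFCS-labelled and 2.53 ± 0.493% in the control-labelled libraries (two-sided exact permutation p = 0.2). Adjusted over the list alone, 16 nuclear genes fell and 6 rose, and 3 mitochondrial genes fell.

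Genes of cholesterol synthesis and uptake were lower in the HFCS-labelled libraries. Of 26 tested, 18 fell and 8 did not pass, with the same counts adjusted over the list alone, with a median of -0.66 and a camera adjusted p of 2.3e-06 (adjusted p = 0.116 with an estimated correlation). The sterol-sensing gene Insig1 had 20.9 ± 1.77 against 93.0 ± 9.07 CPM, and Srebf2, the regulator of these genes, fell by 0.77 on the log2 scale. Of 22 genes of fatty acid synthesis, 11 fell, including Scd1 (-1.30) and Fasn (-0.67), and Dgat1 (0.66), Dgat2 (0.95), Mid1ip1 (0.46) and Gpam (0.38) rose, with a camera adjusted p of 0.0532 (0.0189, a call, with the trend on GC content and length removed, and adjusted p = 0.197 with an estimated correlation). Of 16 targets of the sterol receptor LXR and genes of cholesterol export, 8 rose and Scarb1 (-0.55), Abcg1 (-0.31) and Npc2 (-0.24) fell, with a camera adjusted p of 0.0636 (0.0481, a call, without HFCS replicate 2, also a call at 0.0200 without a filter on low counts, at most 0.121 over the 14 other settings with the preset correlation, and adjusted p = 0.229 with an estimated correlation). Abca1, the exporter of cholesterol to apolipoprotein A-I, had 85.8 ± 7.85 against 11.2 ± 0.601 CPM. Adjusted over the list alone, 13 fatty acid genes fell and 5 rose, and 8 LXR genes rose and 4 fell.

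Among the immediate-early genes, the ATF4 and p53 targets and the unfolded protein response genes that passed the test, more were higher than lower in the HFCS-labelled libraries. Of 28 immediate-early and MAPK feedback genes, 21 rose and Dusp2 (-0.52) fell, with the same counts adjusted over the list alone, with a median of 0.82 and a camera adjusted p of 4.3e-07 (adjusted p = 0.133 with an estimated correlation). The transcription factor gene Fos had 48.9 ± 12.3 against 5.07 ± 0.178 CPM, Klf2 rose by 1.82 and Fosl2 by 1.49 on the log2 scale. Of 40 genes of the integrated stress response under ATF4, 21 rose and 7 fell (22 and 8 adjusted over the list alone), with a camera adjusted p of 0.00440 (adjusted p = 0.335 with an estimated correlation). Trib3 had 208 ± 6.91 against 41.7 ± 8.07 CPM, and Chac1 (2.14), Ppp1r15a (1.66) and Atf3 (1.25) rose. Of 27 p53 targets, 14 rose, including the cell cycle inhibitor gene Cdkn1a (0.79), and Sesn1 (-1.14) fell (15 and 1 adjusted over the list alone), with a camera adjusted p of 0.00524 (adjusted p = 0.181 with an estimated correlation). Of 27 genes of the unfolded protein response, 11 rose and 6 fell, with the same counts adjusted over the list alone, among them Sel1l (0.69) and Edem1 (-0.80), with a camera adjusted p of 0.257.

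Of 20 heat shock genes, 10 fell, Dnajb1 (0.73) rose and 9 did not pass (11 and 1 adjusted over the list alone), with a camera adjusted p of 0.00347 (adjusted p = 0.116 with an estimated correlation). Hsp90ab1 had 1495 ± 52.4 against 2562 ± 56.5 CPM and Hspa8 709 ± 52.0 against 1450 ± 192 CPM. The small heat shock gene Cryab was counted 3 times over the HFCS-labelled and 205 times over the control-labelled libraries, a ratio of 72.1 with a 95% counting interval of 24.3 to 353, and Hspb2 overlaps its position.

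Genes of mitosis were lower in the HFCS-labelled libraries, while genes of DNA replication were not as a group. Of 40 mitotic genes, 38 fell and 2 did not pass, with the same counts adjusted over the list alone, with a median of -0.62 and a camera adjusted p of 4.0e-13 (adjusted p = 0.183 with an estimated correlation). The kinetochore gene Cenpf had 70.9 ± 1.76 against 180 ± 17.0 CPM, the kinesin gene Kif20a 28.0 ± 1.19 against 65.6 ± 2.62 CPM and the checkpoint gene Bub1b 177 ± 6.65 against 329 ± 9.18 CPM. Of 41 genes of DNA replication and S phase, 10 rose, including Tyms (0.61), 10 fell, including Gins3 (-1.39) and Mcm6 (-0.68), and 21 did not pass, with the same counts adjusted over the list alone. Their median was 0.02, their mean -0.02 and their camera adjusted p 0.999. Of 10 replication-dependent histone genes, 6 fell and 4 did not pass, with the same counts adjusted over the list alone, with Hist1h1c at -1.24 and Hist2h2be at -1.90, a median of -1.32 and a camera adjusted p of 0.00107 (adjusted p = 0.116 with an estimated correlation). These histone genes have near-identical copies and are uncertain.

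Of 30 MYC targets and ribosome biogenesis genes, Odc1 (0.59), Nop2 (0.61), Nop58 (0.44), Nip7 (0.56) and Myc (0.84) rose and 10 fell, with the same counts adjusted over the list alone, with a camera adjusted p of 0.360. Of 53 ribosomal protein genes, 6 fell, including Rps4x (-0.36) and Rps25 (-0.30), and 47 did not pass (2 fell adjusted over the list alone), with a median of 0.06 and a camera adjusted p of 0.969.

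Markers of the macrophage itself were more often higher in the HFCS-labelled libraries. Of 22 macrophage identity genes, 14 rose and 4 fell, with the same counts adjusted over the list alone, with a median of 0.43 and a camera adjusted p of 0.00159 (adjusted p = 0.116 with an estimated correlation). The inhibitory receptor gene Sirpa had 272 ± 7.05 against 101 ± 0.536 CPM, and Adgre1, which codes for F4/80, rose by 1.04 on the log2 scale. The growth factor receptor gene Csf1r (-0.67), Cd68 (-0.42), Itgb2 (-0.28) and Laptm5 (-0.17) fell. Of 19 phagocytosis and scavenger receptor genes, 10 rose, including Fcgr1 (1.56), Cd36 (1.05) and Msr1 (0.79), and Axl (-1.99), Mfge8 (-1.09), Anxa1 (-0.59), Havcr2 (-0.58) and Itgax (-1.37) fell, with the same counts adjusted over the list alone, with a camera adjusted p of 0.155. Itgax did not pass without HFCS replicate 2 (edgeR adjusted p = 0.0511) or without control replicate 2 (0.0537). Of 40 lysosome and autophagy genes, 9 rose and 12 fell (10 and 13 adjusted over the list alone), among them Atp6v1a (-0.99) and Lamp1 (-0.84), with a camera adjusted p of 0.606. Of 15 antigen presentation genes, Tap1 (0.55), Tap2 (0.45), B2m (0.39) and Cd74 (0.28) rose and H2-Eb1 (-1.79), H2-T23 (-1.52), Tapbp (-0.73) and H2-DMa (-0.68) fell, with the same counts adjusted over the list alone, with a median of 0.04, a mean of -0.17 and a camera adjusted p of 0.999.

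Markers of other cell types moved both ways. Of 11 osteoclast markers, Ctsk (2.44), Mmp9 (1.07), Traf6 (0.38) and Ostm1 (0.36) rose and Acp5 (-1.16), Nfatc1 (-0.71), Tnfrsf11a (-0.38) and Tcirg1 (-0.37) fell. Their median was -0.04 (-0.225 to 0.145 over the settings tried), their mean 0.12 and their camera adjusted p 0.797. Of 7 dendritic cell markers, Sirpa rose and Cd24a (-3.88) and Itgax fell, with a median of 0.06, a mean of -0.41 and a camera adjusted p of 0.969. The other 5 marker lists had fewer than 5 tested genes and were not tested as lists. Il7r (1.17) and Lck (0.73) rose and Cd5 (-0.47) fell among 4 T and NK cell markers, and Blnk (-0.74) and Ighm (-0.38) fell among 4 B cell markers. Cd5 did not pass without HFCS replicate 2 or 3 or without control replicate 2 or 3 (edgeR adjusted p of 0.0899, 0.149, 0.0899 and 0.0875), nor with library size alone (0.0738), DESeq2 (0.0984) or no filter on low counts (0.0642). Cd2, the other T and NK cell marker, had a log2 fold change of 1.13 (edgeR adjusted p = 0.147) and passed without control replicate 1, at 2.41 (0.00530). Csf3r (1.62) rose and Prtn3 (-0.77) fell among 3 granulocyte and mast cell markers, and Prtn3 did not pass without HFCS replicate 2 (edgeR adjusted p = 0.0565). Col5a1 (-2.03) fell among 3 fibroblast and stromal markers. Cldn4 (-6.34), Pecam1 (-1.86) and Cdh5 (-1.37) fell among 4 epithelial and endothelial markers, and Cdh5 did not pass without HFCS replicate 3 (edgeR adjusted p = 0.0523) or with DESeq2 (0.0574). Cldn4, a tight junction gene, was counted 4 times over the HFCS-labelled and 337 times over the control-labelled libraries. Counts adjusted over the list alone were the same for these 7 lists.

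**Figure D2:**
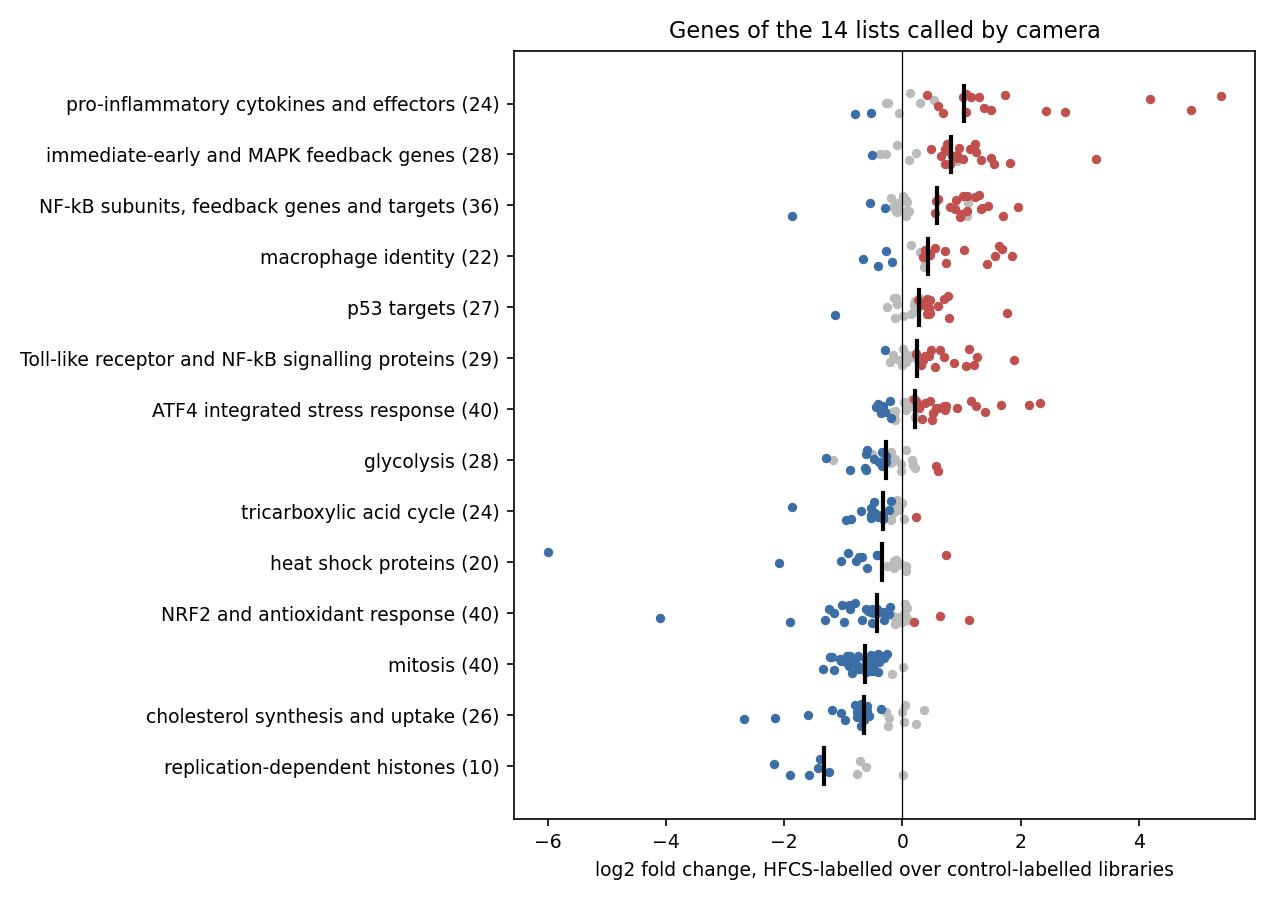
Log2 fold change of HFCS-labelled over control-labelled libraries (horizontal axis) for each tested gene of the 14 lists called by camera (vertical axis, number of tested genes in parentheses), with red points for genes that rose, blue for genes that fell and grey for genes that did not pass the test. The black bar is the list's median, which runs from -1.32 for the replication-dependent histones to 1.05 for the pro-inflammatory cytokines and effectors, and the spread of points shows members that went against their list.

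In all, camera called 14 of 36 tested lists, 7 higher and 7 lower in the HFCS-labelled libraries. With the correlation between genes estimated from these 6 libraries it called 0 lists, the smallest adjusted p being 0.116, while 9 had an unadjusted p under 0.05. The directional test fry, which does not compare a list with other genes, called 28.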

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

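The trend removal on GC content and length, the library sizes without the 10 most abundant genes, and camera with median-of-ratios scaling or the filter of 10 counts in each library were chosen after seeing the data. Across scalings, filters and tests with all libraries, 5913 (DESeq2, with 7090 adjusted p left undefined) to 7296 genes (trend removed) changed, and 5115 to 7550 with a library left out, the highest without control replicate 1. Of the 6447 reported calls, 4982 to 6446 were kept in these settings, and 0 had the other sign. A fold limit of 1.5 gave 3182 genes and one of 4 gave 348 in place of 1528, by construction. Camera, not run with DESeq2 or limma-voom, called 14 to 16 lists in 14 other settings with the preset correlation, the 14 reported lists in each and in some the osmotic stress, LXR, fatty acid synthesis or mitochondrially encoded list, but 0 with an estimated correlation and 28 by fry, which asks another question; the cause of the 0 was not tested further. The replicate block gave 7152 genes, 1563 of them at least 2-fold, and 14 lists. Libraries sharing a number had correlated deviations of 0.17, -0.06 and 0.19, so the numbers are not shown to pair them, and HFCS replicate 2 correlated best with control replicate 1 (0.16). The median log2 fold change changed sign in some setting for 12 lists, 0 of them called by camera. For named genes, 2718 values kept sign and call, 22 lost the call, 6 gained it and 5 changed sign. The sign changes were in uncalled genes: Acta2 at -0.020 under upper-quartile scaling and at -0.023 with the trend removed, and with a library left out Acta2 at -0.14 to 0.16 and Col1a1 at -0.10 to 0.68; the cause was not tested. Depth limits Il6, Cryab and Cldn4, with under 5 counts in 1 group.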

Other observations

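The tests on exchanged labels and on cycling cells were chosen after the results were seen, as were the gene families, and the tests on non-coding genes and the types they cover were set after their medians by gene type had been seen. Of 313 tested zinc finger genes with Zfp symbols, many of them transcriptional repressors, 104 rose and 26 fell in the HFCS-labelled libraries, with a median log2 fold change of 0.19, 0.14 to 0.27 over the settings tried. It was the 1 family of 15 that camera called. Its camera adjusted p was 0.00190, and the call was lost with the correlation estimated (adjusted p = 0.308 with an estimated correlation). Zfp62 had 90.9 ± 4.06 against 46.6 ± 4.53 CPM (mean ± SD, n = 3), and Zfp346 went the other way with 183 ± 1.63 against 326 ± 14.9 CPM. Of 12 host genes of small nucleolar RNAs, 7 rose and 1 fell, with a camera adjusted p of 0.151. Snhg1 (1.02) and Snhg12 (1.73) were among those that rose. Small nucleolar RNA genes themselves had 17 of 46 lower, at a median of -0.62. Other non-coding types were lower too, with medians of -0.65 for sense intronic, -0.43 for antisense and -0.25 for intergenic genes. An opposite change of these RNAs and their hosts is therefore not shown. Of 59 protein phosphatase genes with Ppp symbols, 26 rose and 7 fell (camera adjusted p = 0.0550). Of 9 annexins, 5 fell, among them Anxa5 (-0.98), and Anxa3 rose by 2.55 on the log2 scale. The medians of these host, phosphatase and annexin genes kept their sign in every setting tried.

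A few genes outside the naming rule were chosen after their values were seen, in part because they were lower in the HFCS-labelled libraries, so they show no pattern by themselves. Aqp1, Ranbp3l and Nfat5 belong to the osmotic stress response list above and add nothing beyond it, while Fxyd2 is not in that list. Fxyd2, a regulator of the sodium pump, had 96.2 ± 2.99 against 1205 ± 218 CPM, the water channel gene Aqp1 0.474 ± 0.0819 against 8.49 ± 0.899 CPM and Ranbp3l 3.01 ± 0.924 against 18.1 ± 3.88 CPM. Nfat5, which codes for the transcription factor of the response to tonicity, had 1079 ± 54.2 against 1176 ± 163 CPM and did not pass the test (edgeR adjusted p = 0.319).

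The tonicity-response genes Akr1b3, Slc5a3, Slc6a12, Slc6a6 and Hspa4l, picked after their values were seen, had a median log2 fold change of -1.78 in the HFCS-labelled libraries. An exchange of the group labels cannot be told apart from a true difference: it would put these genes in the direction known for added solute, but it would also make Txnip and Arrdc4, which glucose raises, lower in sugar (their median was 1.23 as labelled). Both sets are picked members of longer lists. Txnip and Arrdc4 were the only 2 of 10 tested MondoA and ChREBP genes that rose, while 3 fell. Among 23 tested genes of the osmotic stress response, 11 fell and 4 rose. A difference in the tonicity of the media stays open and untested. So does a loss, after 18 h with HFCS, of a response already present in the control-labelled cells. A response to HFCS that had merely lapsed by 18 h would return these genes to the control level. The median of -1.78 for the 5 picked genes lay below that level and argues against such a lapse alone, as labelled.

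The mitosis genes had a median log2 fold change of -0.62 in the HFCS-labelled libraries. A bias on GC content or length is argued against as the whole cause, since with each library's trend removed the median was -0.61, 39 of 40 genes were lower past the threshold and the camera adjusted p was 4.2e-13 (adjusted p = 0.163 with an estimated correlation). Fewer cycling cells cannot be told apart from a change in mitotic genes alone, since 2 lists tied to S phase differed. The S-phase list as a set was not lower, with a median of 0.018, 10 of 41 genes higher and 10 lower. The SD of 0.354 among its members is a spread between genes and not the error of that median. The replication-dependent histones had a median of -1.32 with 6 of 10 lower past the threshold (camera adjusted p = 0.00107, and adjusted p = 0.116 with an estimated correlation). They are uncertain for their near-identical copies, and only 10 of the 21 in the data passed the count filter, so they are a weak measure of S phase. Cdkn1a, a cell cycle inhibitor, rose by 0.79 on the log2 scale. A lower share of cells in G2 and M phase alone stays open and was not tested.

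Among 1497 tested non-coding genes (antisense, intergenic, sense intronic, bidirectional and 423 unconfirmed entries of type TEC, of which 156 were lower and 22 higher), 443 were lower and 100 higher in the HFCS-labelled libraries, and among 226 processed transcripts, which were left out, 60 were lower and 37 higher. Low abundance is argued against as the cause, since their median lay at -0.40 relative to protein-coding genes matched on mean level (1488 each, permutation p = 1e-05, the smallest 100000 resamples can give), -0.38 with the processed transcripts added and -0.35 without the TEC entries. Permutations in this paragraph shuffled genes, which are not independent replicates, so their p does not measure the spread between libraries. Genomic DNA in the control-labelled libraries, which would reach all positions alike, cannot be told apart from other causes. Genes overlapping a protein-coding gene lay at -0.37 relative to those over 10 kb away (908 against 252, permutation p = 1e-05). This difference was -0.32 with the processed transcripts added and -0.26 without the TEC entries. By the rule set for this test, a difference of this size counted against genomic DNA. That reading is not kept here. The overlapping and far genes were not matched on level or length, on which the effect of such DNA would depend, so their difference cannot decide. Genes below the filter summed to 1800 to 1887 CPM in control-labelled and 1510 to 1600 CPM in HFCS-labelled libraries. Transcription running past gene ends cannot be told apart from its absence, since genes downstream of a protein-coding gene differed from far ones by -0.047 with a bootstrap SE of 0.0796 (156 against 252, permutation p = 0.580). Unspliced RNA of the overlapped genes may add to the difference at -0.37 and was not tested. The other 181 genes lay within 10 kb upstream of a tested protein-coding gene, and neither overlapped one nor lay downstream of one. Their median was -0.47 (51 lower, 6 higher), against -0.51 for overlapping, -0.20 for downstream and -0.15 for far genes. The lower level was therefore not confined to genes that overlap a protein-coding gene.

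In 1 of the 10 splits of the 6 libraries, the labelled one, as many as 6447 genes passed edgeR's quasi-likelihood test, and the highest of the other splits gave 0, or 90 with DESeq2 and 0 with limma-voom. The splits other than the labelled one gave 60 to 1131 genes with an unadjusted p under 0.05, the highest with HFCS replicates 1 and 2 and control replicate 1 together. With 10 splits the share cannot be under 0.1. Every other split mixes HFCS-labelled and control-labelled libraries on each side. The labelled difference then adds to the spread within its groups, so few calls follow by construction and their number is no measure of chance.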
